A study of Mus musculus with 8 samples.

How the data were processed

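RNA was measured by short-read sequencing in migratory dendritic cells, the antigen-presenting cells that carry skin antigens to lymph nodes. Per the labels, they came from skin-draining lymph nodes of mixed bone-marrow chimeras, mice whose blood cells were rebuilt after irradiation from an equal mix of a competitor marrow and a donor marrow. The competitor marrow and the hosts carried the CD45.1 form of the leukocyte surface protein CD45. The donor marrow carried CD45.2 and was either Etv3+/+ or Etv3-/-. Host cells that outlived the irradiation carry CD45.1 and would be sorted with the competitor cells. Nodes were digested with collagenase D, and live CD11c+ cells with high MHC class II were sorted after exclusion of cells with markers of T cells, B cells, natural killer cells, eosinophils and neutrophils, per the labels' protocols. Libraries were made with a low-input SMART-Seq HT kit, which amplifies cDNA by PCR without molecular identifiers and does not mark the strand.

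The 8 libraries formed 4 groups of 2: WT donor and WT-set competitor cells from chimeras with Etv3+/+ donor marrow, and KO donor and KO-set competitor cells from chimeras with Etv3-/- donor marrow. The name KO donor stands for the label only, as described with the Etv3 values. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.7.3a, featureCounts from Subread 1.6.3, DESeq2 1.26.0 and the mouse build mm10 were used. The gene annotation, the strand setting and the filters are not given in the sources used here. The deposited values are a normalized signal for 27678 genes in each library, which is not whole. Every value was a whole multiple, within a tolerance of 0.05 reads, of 1 step per library, so that whole reads were recovered for 100% of the values. A read stood for 0.722 to 1.23 normalized counts, depending on the library. Recovered totals ran from 129334701 to 204016708 reads per library, and 7867 genes had 0 reads in every library. Gene positions came from GENCODE M21 on GRCm38, in which 26904 of the symbols (97.2%) had exactly 1 position.

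Log2 values with a pseudocount of 2 were fitted with limma 3.58.1 in R 4.3.3 (limma-trend), with all 8 libraries in 1 fit, for the 16112 genes with a mean of at least 10 normalized counts. The fit had 4 residual degrees of freedom and a prior worth 5.40. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values without another tool's name come from this fit, from camera or, for mean levels of gene lists, from a limma fit of those means. The 6 comparisons were KO donor against WT donor, KO donor against KO-set competitor, WT donor against WT-set competitor, the difference between the last 2 named donor effects, KO-set competitor against WT-set competitor, and KO donor against the mean of the 3 other groups. Gene lists, 37 in number, covered dendritic cell functions, other cell types that a sort from lymph nodes could hold, and sample quality. They were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with a correlation estimated from the data, and p-values were adjusted over the lists. The groups, comparisons, tests of genes, camera tests, gene lists and the rule for naming genes were fixed before the data were examined. Mean log2 levels of each list were also compared with limma, which was not part of that plan.

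Named genes were the 10 largest rises and falls among called genes in each of the 2 main comparisons (the first 2 named) and the 5 largest each way in the others. Both libraries of 1 side had to lie above both of the other, and the higher group mean had to reach 50 normalized counts. Where fewer passed, up to 5 each way with the smallest p were named as not passed. Predicted genes, receptor segments and pseudogenes were left out of the naming only. Up to 4 members with the smallest p were taken from each list, and 13 genes of dendritic cell biology and Etv3 itself could always be named. Where a group had 0 reads, the fold is a lower bound against 3 reads over the group, and with 1 to 3 reads the ratio has a 95% counting interval. Leaving out 1 library of the group at 0 reads lowers each bound by 1.64 to 2.57 times by construction. Floors and intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The p-values measure only the spread between these libraries, and the labels do not state whether the replicates of a group came from separate mice.

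Within a set, donor and competitor cells come from the same kind of mixed chimera, and libraries with the same number were taken as pairs from the same mice in an alternative fit. Their deviations from the group means correlated across genes by -0.0264 in the WT set and 0.0529 in the KO set, and all pairings of groups lay between -0.0425 and 0.0615. Counts were simulated for the 16112 genes, with 200 genes changed, all from those with a mean of at least 50. KO donor against WT donor recovered 3.50% of genes changed by 1 on the log2 scale, 46.4% at 2 and 62.0% at 3. Recovery of genes with lower means was not simulated. On average 3 unchanged genes per run were called in this comparison and 4.4 in KO donor against KO-set competitor. The shares recovered at 1, 2 and 3 were 3.79%, 45.8% and 62.3% for KO donor against KO-set competitor. They were 0.583%, 17.9% and 43.3% for the difference of donor effects, and 12.2%, 57.4% and 69.2% for KO donor against the other groups. Camera was tested on simulated data for KO donor against WT donor, in which every gene varied independently. It called a list of 25 genes shifted by 1 in 100% of 50 runs and an unshifted list in 2%. These shares do not cover lists whose genes vary together, such as the ribosomal protein genes, with an estimated correlation of 0.679. The alternatives were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, another pseudocount, added TMM factors, other filters on low values, replicate blocks, fits of the compared groups alone, and each library left out in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the values and drew the figures.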

Results

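Gene expression was measured in migratory dendritic cells sorted from the skin-draining lymph nodes of mixed bone-marrow chimeras, in 4 groups of 2 libraries. Donor cells were compared with competitor cells that had grown in the same kind of host, for donor marrow labelled Etv3+/+ and Etv3-/-. The series title names Etv3, an ETS-family transcriptional repressor, and the tolerance-promoting function of dendritic cells as its subject. Depth was 144100525 and 144607572 reads in the WT-set competitor libraries and 204016708 and 140609176 in WT donor. It was 156623828 and 136849616 in KO-set competitor and 129334701 and 183744560 in KO donor. The 10 most abundant genes took 7.92% to 9.49% of the reads of a library. The reads carry no molecular identifiers, so the number of molecules behind a count was not measured. Values are normalized counts, given as mean ± SD with n = 2 libraries per group.

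Etv3 RNA was not called as lower in the libraries labelled KO donor, although both lay below all 4 libraries of WT donor and KO-set competitor. Etv3 (chromosome 3, 87525407 to 87540156, GRCm38) had 264258 and 253678 normalized counts in the KO donor libraries and 282524 and 277147 in WT donor. It had 271078 and 286549 in KO-set competitor and 265270 and 200319 in WT-set competitor. The log2 difference between KO donor and WT donor was -0.11 (SE 0.28, adjusted p = 0.914), and that between KO donor and KO-set competitor was -0.11 (adjusted p = 0.953). The part of the gene that the knockout allele removes is not given in the sources used here, and a count over the whole gene does not check the labels when the rest of the transcript is still made. KO donor therefore stands below for the libraries labelled Etv3-/-, and every direction given for it rests on that label. Etv6, a related ETS repressor, differed by 0.24 between KO donor and WT donor (adjusted p = 0.738).

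KO donor against WT donor asks how donor dendritic cells labelled Etv3-/- differ from Etv3+/+ donor cells of other chimeras. The called genes included 4 of 14 measured ligands that co-stimulate T cells, each higher in KO donor, and 10 of 24 genes of the cholesterol list, each lower. That list covers cholesterol synthesis but also holds Ldlr, the receptor for low-density lipoprotein, which was among the 10. Cd86 (chromosome 16, 36603869 to 36666081), a ligand of the T cell receptors CD28 and CTLA-4, stood at 81344 ± 14612 in KO donor and 28604 ± 3490 in WT donor, 2.83-fold higher (log2 1.501, SE 0.25, adjusted p = 0.0245). Cd80 (chromosome 16, 38455561 to 38496335), which binds the same receptors, rose from 4935 ± 1554 to 15210 ± 1944, a 3.15-fold difference (log2 1.65, SE 0.31, adjusted p = 0.0352). Sqle (chromosome 15, 59315077 to 59331192), squalene epoxidase, fell from 18672 ± 6168 to 2756 ± 328 (log2 -2.72, adjusted p = 0.00427). Aldh1a2 (chromosome 9, 71215789 to 71296243), an enzyme that makes retinoic acid, fell from 13849 ± 5780 to 2477 ± 173, 5.35-fold lower (log2 -2.42, SE 0.44, adjusted p = 0.0327).

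Of the 14 measured co-stimulatory ligands, 4 rose, 0 fell and 10 were not called (6 and 0 adjusted over the list alone). Tnfsf4 (chromosome 1, 161395409 to 161418410), the OX40 ligand, went from 837 ± 252 to 9175 ± 272 (log2 3.48, adjusted p = 0.00664). Tnfsf15, a ligand that co-stimulates T cells through DR3, went from 342 ± 43.4 to 2466.5 ± 30.7 (log2 2.85, adjusted p = 0.0392). It was also higher in the KO-set competitor than in the WT-set competitor, without passing. The list's median was 1.35 (camera adjusted p = 5.41e-07, adjusted p = 0.246 with an estimated correlation). Among 24 measured genes of the cholesterol biosynthesis list, 0 rose, 10 fell and 14 were not called (0 and 16 adjusted over the list alone). The median was -1.48 (camera adjusted p = 6.11e-16, adjusted p = 0.0687 with an estimated correlation). Cyp51, the lanosterol demethylase, fell by 2.22, Sc5d, a sterol desaturase, by 2.10, and Hmgcs1 (chromosome 13, 119690379 to 119708260), which makes HMG-CoA, fell by 2.35 on the log2 scale. Camera called 13 of the 37 lists, and none of the 13 was called with an estimated correlation. The 13 included glycolysis, with 0 calls among 21 (median 0.38, and 0.21 and 0.63 without WT donor 1 and KO donor 2, camera adjusted p = 0.0135). They also included the sex-linked genes, where the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were measured and 0 were called. All 4 were lower in KO donor (median -0.98, and -0.39 without KO donor 1, camera adjusted p = 0.0234), and the cause was not tested.

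Co-inhibitory and tolerance-associated genes moved both ways. Of 27 measured, 2 rose and 2 fell (4 and 4 adjusted over the list alone). The median was 0.10 and the mean -0.14 (camera adjusted p = 0.433). Itgb8 (chromosome 12, 119158022 to 119238802), an integrin chain that activates TGF-beta, fell from 5630.1 ± 135 to 743 ± 15.4 (log2 -2.92, adjusted p = 0.00427). Havcr2 (chromosome 11, 46454935 to 46481255), which encodes the inhibitory receptor TIM-3, rose from 2502 ± 255 to 15001 ± 1461 (log2 2.58, adjusted p = 0.00427). Nectin2, a ligand of TIGIT and CD226, rose by 3.00 on the log2 scale (adjusted p = 0.00693). Cd274, which encodes PD-L1, differed by 0.92 and did not pass (adjusted p = 0.295). Of 20 inflammatory cytokines, 2 rose and 1 fell (5 and 1 adjusted over the list alone). Their median was 0.75 (camera adjusted p = 0.0155, and 0.0734 without KO donor 2; adjusted p = 0.246 with an estimated correlation). Il27 and Ebi3, the subunits of IL-27, rose by 2.54 (adjusted p = 0.0228) and 1.59 (adjusted p = 0.0317). The Il27 difference was 1.92 without WT donor 1 and 3.16 without WT donor 2. Apobr, a neighbour of Il27, overlaps it, so the Il27 value is uncertain. Csf1, a macrophage growth factor, fell by 1.99 (adjusted p = 0.041). Il12b, the shared subunit of IL-12 and IL-23, differed by 1.42 without passing (adjusted p = 0.11). Among 17 genes that polarize helper T cells or attract regulatory T cells, 3 rose and 0 fell (5 and 1 adjusted over the list alone). These were Tnfsf4, Il27 and Ebi3, and the list was not called (camera adjusted p = 0.0913).

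Of 16 MHC class II genes, 1 rose and 0 fell (8 and 0 adjusted over the list alone). This was H2-DMa, which helps load peptides (18307 ± 1395 to 56316 ± 8869; log2 1.61, adjusted p = 0.0141). The list's median was 0.74 (camera adjusted p = 2.23e-06, adjusted p = 0.246 with an estimated correlation). Of 38 migration and cytoskeleton genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 0.42 (camera adjusted p = 1.66e-05, adjusted p = 0.246 with an estimated correlation). They included Itgax, which encodes CD11c (log2 1.94, adjusted p = 0.0117), the integrin chains Itgb7 (1.32) and Itgb2 (1.63), and Vasp, an actin regulator (1.70). Ccr7, the receptor that guides these cells to lymph nodes, differed by 0.06 (adjusted p = 0.985), Cd40 by 0.03 (0.987) and the chemokine Ccl22 by 0.21 (0.857). Of 25 chemokines, Cxcl9, which attracts T cells through CXCR3, rose by 3.24 (adjusted p = 0.0156), while Ccl9 (-2.35, adjusted p = 0.0305) and Cxcl1 (-2.21, adjusted p = 0.043) fell. For Cxcl1, WT donor was the high group, at 80142 ± 51517 against 15449 in KO donor and 5255 and 5410 in the WT-set and KO-set competitors. The Cxcl1 difference was -1.51 without WT donor 1 and -2.92 without WT donor 2. The chemokine list was not called (2 and 6 adjusted over the list alone; camera adjusted p = 0.164). The mature migratory program, a list of 36 genes common to dendritic cells that leave tissues, had 1 rise and 3 falls (2 and 6 adjusted over the list alone). Its median was -0.03 (camera adjusted p = 0.415), and Socs2, a regulator of cytokine signals, fell by 1.46 on the log2 scale. Of 21 ETS genes, 1 rose and 1 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.11). Ehf, an epithelial and dendritic cell factor, fell from 32886 ± 11617 to 2018.5 ± 52.8 (log2 -3.98, adjusted p = 0.00452), and Elk3 rose by 1.10 (adjusted p = 0.0442). Of 28 dendritic cell transcription factors, 0 rose and 1 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.611), namely Prdm1, a repressor also called Blimp-1 (-2.68, adjusted p = 0.016).

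Cd207, which encodes langerin, a protein of Langerhans cells and some dermal dendritic cells, rose from 3728 ± 336 to 22838 ± 1731 (log2 2.62, adjusted p = 0.00994), with 10957 and 11617 in the WT-set and KO-set competitors. It was 1 of 2 rises among 13 Langerhans cell markers (5 and 2 adjusted over the list alone; median 0.84, and 0.50 without KO donor 2, camera adjusted p = 0.00373, adjusted p = 0.246 with an estimated correlation). Mean log2 levels of this list were 11.67 and 11.84 in WT donor and 12.11 and 12.05 in its competitor. Camera called the list downward between these 2 groups (median -0.17, and 0.04 without WT donor 1, camera adjusted p = 0.0312, adjusted p = 0.702 with an estimated correlation). Between KO donor and KO-set competitor it was not called (camera adjusted p = 0.0853). T cell markers had 1 rise among 24, Foxp3 (log2 1.78, adjusted p = 0.0475), and 0 falls (2 and 0 adjusted over the list alone). Their median was 0.65, and 0.43 and 0.98 without WT donor 1 and 2 (camera adjusted p = 1.64e-05, adjusted p = 0.393 with an estimated correlation). B cell markers had 0 calls among 23 (0 adjusted over the list alone; median -0.11, camera adjusted p = 0.415). The cDC1 markers had 0 among 23 (1 and 0 adjusted over the list alone; camera adjusted p = 0.917). Markers of cDC2 had 1 rise among 24, Il1r2, a decoy receptor for IL-1 (4 and 0 adjusted over the list alone). Their median was 0.30, and 0.54 without KO donor 1 (camera adjusted p = 0.0266, adjusted p = 0.246 with an estimated correlation). This call was lost without WT donor 2, either KO-set competitor library or either KO donor library (adjusted p up to 0.116). Immediate early and dissociation genes, which respond to handling of tissue, had 2 rises among 30, Klf2 (1.86) and the heat-shock gene Dnajb1 (1.33), with 6 and 0 adjusted over the list alone. Both also stood high in the KO-set competitor, at 40315 ± 5076 and 60844 ± 13728. The list's median was 0.64 (camera adjusted p = 1.44e-07, adjusted p = 0.246 with an estimated correlation). Ribosomal protein genes had 0 calls among 83 (0 adjusted over the list alone) with a median of 0.47 (camera adjusted p = 3.35e-09, adjusted p = 0.65 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 0 among 54 (0 adjusted over the list alone) with a median of 0.31 (camera adjusted p = 6.13e-05, adjusted p = 0.65 with an estimated correlation).

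The largest fitted changes belonged to genes at or near 0 reads on 1 side. Kirrel2, an adhesion protein that resembles nephrin, was at least 657-fold lower in KO donor, Itgb2l, an integrin chain, at least 768-fold, and Bpifb2, a lipid-binding protein, at least 592-fold. Pcdh18, a protocadherin, was at least 826-fold lower, Evc at least 383-fold and Slco2b1, an organic anion transporter, at least 355-fold. F9, which encodes coagulation factor IX, had 1320 in WT donor and 3.68 ± 5.21 in KO donor, and Arsi, a sulfatase, had 1149 and 1.67. Ddit4l was 671-fold lower on 3 reads (interval 203 to 2886) and Nap1l3 was 1236-fold lower on 1 read (306 to 67483). Upward, Stac, an adaptor protein, was 3248-fold higher on 1 read in WT donor (758 to 167020), and Amotl1, a junction protein, stood at 4950 ± 315 against 57.8 ± 81.7. Against 0 reads in WT donor, Glb1l2 was at least 789-fold higher, Syde2 at least 487-fold and Plagl1 at least 399-fold. Zfp423 was at least 340-fold higher, Grin3b at least 204-fold and Dthd1 at least 185-fold. Adrb1 (1261 against 15.3 ± 21.6) and Tdrd5 (1368 against 19.8) completed the rises. In the group near 0, all reads came from 1 library for Adrb1, Tdrd5, Amotl1 and Stac (WT donor 2), Arsi and Ddit4l (KO donor 2) and F9 and Nap1l3 (KO donor 1), and the other library had 0. Without WT donor 1 the WT donor values were 30.6 for Adrb1, 39.6 for Tdrd5 and 116 for Amotl1. Several bounds rested on 1 library. Without KO donor 1 and 2 they were 1291 and 287 for Glb1l2, 679 and 294 for Syde2, 568 and 111 for Zfp423, and 86.3 and 321 for Grin3b. Without WT donor 1 and 2 they were 1246 and 290 for Itgb2l, 859 and 326 for Bpifb2, and 235 and 476 for Slco2b1, and Nap1l3 stood in WT donor at 356 and 1162. Several of these were also present in the WT-set competitor, with 207.6 for Glb1l2 and 264 for Plagl1, so that for them the WT donor libraries were the low ones.

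In all, 272 genes differed, 156 higher and 116 lower in KO donor (2184 at an unadjusted p under 0.05), and 24 of the 272 had a group mean of 0. The count was 170 with edgeR, 1037 with DESeq2, 121 without a filter and 0 in a fit of these 4 libraries alone. Most or all of the 272 calls were lost when any 1 library was left out, which leaves a group of 1. Without KO donor 1 the genes still called were nearly all lower in KO donor and mostly not among the 272. All 272 kept their sign in the 4 fits that left out a library of the compared groups. They were chosen by their p in the same libraries, so kept signs were likely from the start and add no evidence.

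**Figure D1:**
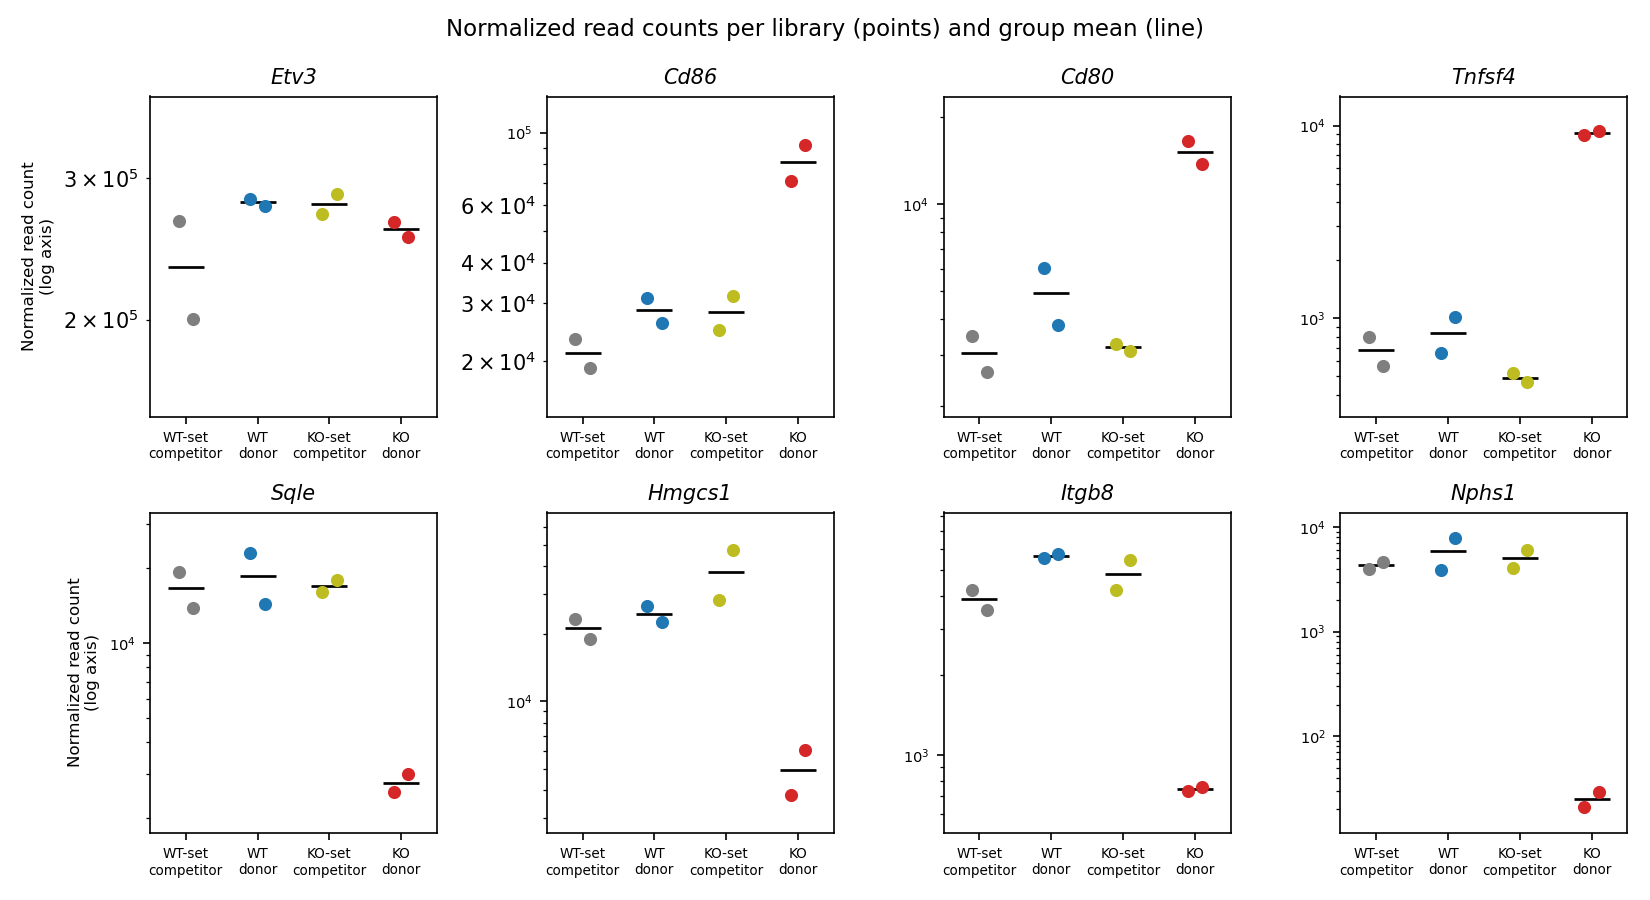
Normalized counts on a log axis for Etv3 and 7 genes that differ in KO donor, with 1 point per library, 2 libraries per group and a line at each group mean. Etv3 lies between 200319 and 286549 in all 8 libraries, while the KO donor means are 81344 for Cd86, 2756 for Sqle, 743 for Itgb8 and 25.03 for Nphs1.

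KO donor against KO-set competitor asks how the cells labelled Etv3-/- differ from competitor cells of the same kind of chimera, although the labels do not tie both to the same mice. Here the called genes included 4 of 14 co-stimulatory ligands, each higher in KO donor, and 10 of 24 cholesterol genes, each lower. Cd80 was 4.73-fold higher in KO donor than in the competitor (15210 ± 1944 against 3200.1 ± 121; log2 2.24, adjusted p = 0.0123), and Cd86 rose by 1.53 on the log2 scale (adjusted p = 0.0251). Il12b was 4.14-fold higher (94821 ± 5872 against 23693 ± 8592; log2 2.05, adjusted p = 0.0336, and 0.0883 with the chimera as block). Hmgcs1 fell from 37747 ± 13360 to 4944 ± 1596 (log2 -2.92, adjusted p = 0.00662). Aldh1a2 differed by -1.09 and did not pass (adjusted p = 0.357).

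Of 14 co-stimulatory ligands, 4 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.95, and 0.63 without KO donor 2 (camera adjusted p = 1.34e-06, adjusted p = 0.141 with an estimated correlation). Tnfsf4 rose by 4.21 (adjusted p = 0.00662), and Cd48, a ligand of CD2 and 2B4, by 1.15 (adjusted p = 0.048, and 0.0853 with the chimera as block). Tnfsf15, called against WT donor, was not called here. Of 24 cholesterol genes, 0 rose and 10 fell (0 and 19 adjusted over the list alone), among them Sqle (-2.63), Sc5d (-2.06) and Msmo1, a sterol oxidase (-2.30). Their median was -1.87 (camera adjusted p = 2.92e-20, adjusted p = 0.0369 with an estimated correlation). Havcr2 rose by 2.81 (adjusted p = 0.00662) and Nectin2 by 2.87 (adjusted p = 0.0115), while Itgb8 fell by 2.68 (adjusted p = 0.00662). Pdcd1lg2, which encodes the inhibitory ligand PD-L2, rose by 1.94 (adjusted p = 0.0296, and 0.078 with the chimera as block). These were the 3 rises and the fall among 27 tolerance-associated genes (5 and 1 adjusted over the list alone). The list's median of -0.11 and its camera direction, upward, differed in sign (camera adjusted p = 0.204). MHC class II genes had 2 rises among 16 (10 and 0 adjusted over the list alone; median 0.83, camera adjusted p = 2.49e-08, adjusted p = 0.187 with an estimated correlation). H2-DMa rose by 1.63 and H2-Eb2 by 1.78 (adjusted p = 0.0291, and 0.0651 with the chimera as block). H2-Eb2 is uncertain, since it can share reads with related class II genes. Cytokines had 2 rises among 20, Ebi3 and Il12b (7 and 1 adjusted over the list alone; camera adjusted p = 0.00135, adjusted p = 0.141 with an estimated correlation). Ebi3 rose by 1.625 (adjusted p = 0.0319, and 0.0607 with the chimera as block). Cxcl9 rose by 4.18 (adjusted p = 0.00662). Interferon-stimulated genes had 1 rise among 48, Oasl2 (2.00, adjusted p = 0.025, and 0.06 with the chimera as block), and 0 falls (4 and 1 adjusted over the list alone). Their median was 0.46 (camera adjusted p = 0.000254, adjusted p = 0.102 with an estimated correlation).

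Markers of cDC2 cells, the dendritic cells that mainly prime helper T cells, had 3 rises and 0 falls among 24 (11 and 1 adjusted over the list alone). Their median was 1.35 (camera adjusted p = 1.85e-09, adjusted p = 0.0369 with an estimated correlation). Cd300a, an inhibitory receptor of myeloid cells, stood at 4378 ± 1930.5 in KO donor and 290 ± 55.1 in the competitor (log2 3.85, adjusted p = 0.00662), and its WT donor mean was 1950. The KO-set competitor libraries were the low ones for this list, with mean log2 levels of 10.17 and 9.42, against 10.79 to 11.03 in the WT groups and 11.38 and 11.29 in KO donor. Between KO donor and WT donor the list's mean differed by 0.45 (adjusted p = 0.364). Ms4a6c, a membrane protein of myeloid cells, rose by 3.01 (adjusted p = 0.0227, and 0.0649 with the chimera as block). Monocyte and macrophage markers had 4 rises and 1 fall among 27 (11 and 2 adjusted over the list alone; median 0.95, and 1.57 without KO donor 2, camera adjusted p = 1.34e-06, adjusted p = 0.209 with an estimated correlation). Their mean log2 levels were 8.68 and 8.22 in the KO-set competitor, 8.98 to 10.08 in the WT groups and 9.50 and 9.14 in KO donor, which differed from WT donor by -0.39 (adjusted p = 0.558). Cd68, a lysosomal protein, rose by 2.10 and Lyz2, lysozyme, by 1.94. Markers of natural killer and innate lymphoid cells had 1 rise and 0 falls among 21 (3 and 0 adjusted over the list alone), Klrk1, an activating receptor (1.90, adjusted p = 0.0234, and 0.0502 with the chimera as block). Their median was 0.39, and 0.70, 1.15 and 0.60 without KO-set competitor 2, KO donor 1 and KO donor 2 (camera adjusted p = 0.00272, and 0.161 without KO donor 2; adjusted p = 0.515 with an estimated correlation), and the KO-set competitor libraries were again the low ones (mean log2 levels of 7.86 and 8.05, against 8.74 to 10.44 elsewhere). T cell markers had 0 calls among 24 (0 adjusted over the list alone) and a median of 0.33 (camera adjusted p = 0.0132, adjusted p = 0.564 with an estimated correlation). The T cell call was lost without KO-set competitor 1 (median 0.16, adjusted p = 0.412) or KO donor 2 (median 0.18, adjusted p = 0.176) and with DESeq2 (adjusted p = 0.0600). Immediate early and dissociation genes had 0 calls among 30 (0 adjusted over the list alone; median 0.14, camera adjusted p = 0.0927). Nphs1 (chromosome 7, 30458315 to 30487223), which encodes nephrin, an adhesion protein best known from the kidney filter, fell from 5015 ± 1360 to 25.03 ± 5.87 (log2 -7.53, SE 0.48, adjusted p = 0.000814).

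The largest rises from 0 reads in the competitor were Il17f, a cytokine, at least 636-fold higher, Bex6 at least 311-fold, Pilrb2 at least 257-fold and Cd300lb at least 190-fold. The myeloid receptors Trem2, Fcgr1 and Trem1 were at least 151-fold, 95.2-fold and 74.9-fold higher. Col4a2, a basement membrane collagen whose gene overlaps Col4a1 and is therefore uncertain, was 1081-fold higher on 3 reads (341 to 4838). Pde10a was 1221-fold higher on 1 read (201 to 44258), and Il17rb stood at 881 against 17.9. The KO-set competitor was the low group for several of these. In the WT-set competitor, WT donor and KO donor, Il17f had 502, 615 and 963 normalized counts, Cd300lb 119, 415 and 287, Fcgr1 137, 171 and 144, and Trem1 347, 310 and 113. Except for Il17f, each of these 10 lost its call with the chimera as block (adjusted p from 0.051 to 0.116). The falls to 0 reads were Itgb2l, at least 699-fold lower, Sox13 at least 538-fold, Kirrel2 at least 395-fold and Bpifb2 at least 300.5-fold. Crisp3 was at least 496-fold lower (adjusted p = 0.0246, and 0.0546 with the chimera as block). Lamc2, a laminin chain, was 726-fold lower on 3 reads (297 to 4210), F9 fell from 1322 to 3.68, Arsi from 722 to 1.67 and Card14 from 2271 to 29.2 ± 41.3. In KO donor, all reads of Card14 and Arsi came from library 2 and all of F9 and Lamc2 from library 1, so that Card14 stood at 58.4 without KO donor 1 and at 0 without KO donor 2. Without KO donor 1 and 2 the bounds were 258 and 1014 for Il17f and 122 and 393 for Pilrb2, and Pde10a stood in KO donor at 123 and 1215. Without KO-set competitor 1 and 2 they were 420 and 977 for Itgb2l, 772 and 221 for Crisp3, 188 and 601 for Kirrel2, and 188 and 413 for Bpifb2, and Il17rb stood in the competitor at 34.0 and 1.87.

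In all, 207 genes differed, 115 higher and 92 lower in KO donor (1955 at an unadjusted p under 0.05), and with the chimera as block 96 did, 60 higher and 36 lower, 90 of them among the 207. The count was 119 with edgeR, 876 with DESeq2, 112 without a filter and 0 in a fit of these 4 libraries alone, and 23 of the 207 had a group mean of 0. Most or all of the 207 calls were lost when any 1 library was left out, which leaves a group of 1. Without KO donor 1 the genes still called were all lower in KO donor and mostly not among the 207. All 207 kept their sign in the 4 fits that left out a library of the compared groups. Here too the genes were chosen by their p in the same libraries, so kept signs add no evidence.

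Both comparisons of KO donor called 70 genes as higher and 72 as lower, and 0 in opposite directions. Independent lists would share 1.11 and 0.662 genes. In 100 simulations with no effect and the shared KO donor libraries, the genes with the smallest p, taken in the same numbers and directions as the calls, shared 23.4 (15 to 31) and 17.4 (11 to 25) on average, a comparison chosen after the overlap was seen. Every gene varied independently in these simulations, so their ranges do not cover genes that vary together within the shared libraries. Part of the excess may come from the KO donor libraries, which both comparisons share.

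The difference between the donor effects of the KO set and the WT set asks whether donor and competitor cells differ more where the donor is labelled Etv3-/-. Nphs1 alone passed, with 25.03 ± 5.87 in KO donor and group means from 4320 to 5858 elsewhere (log2 -7.88, SE 0.68, adjusted p = 0.0120). The gene Nphs1os lies inside Nphs1 on the other strand and, with no strand setting stated, may share its reads. As a list, cholesterol biosynthesis had 0 calls among 24 (0 and 16 adjusted over the list alone) and a median of -1.73 (camera adjusted p = 1.46e-15, adjusted p = 0.0542 with an estimated correlation). Its mean log2 level differed by -1.64 (adjusted p = 0.0160) in the limma fit of list means, which was not planned. Co-stimulatory ligands had a median of 0.93, and 0.57 without KO donor 2 (4 and 0 adjusted over the list alone; camera adjusted p = 5.26e-05, adjusted p = 0.266 with an estimated correlation).

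Not passed, each with an adjusted p of 0.0905, were Serpina3g (2.497), a protease inhibitor with close paralogs that leave its reads uncertain, Lpcat2 (4.15), a phospholipid enzyme, Havcr2 (2.86), Ly86 (2.03), a partner of the receptor RP105, and Gngt2 (3.20), which overlaps Abi3 and is uncertain. On the lower side these were Itgb8 (-3.23), Hmgcs1 (-3.14), Rnf19a (-2.17), F9 and Arsi, the last 2 with 3.68 and 1.67 normalized counts in KO donor, in each case from 1 library with the other at 0. Cd86 (1.09, adjusted p = 0.456), Cd80 (1.58, adjusted p = 0.334), Il12b (1.79, adjusted p = 0.364) and Aldh1a2 (-1.46, adjusted p = 0.593) were not called here, so that their differences in KO donor were not shown to exceed those between WT donor and its competitor. The count of 1 (1325 at an unadjusted p under 0.05) was 1 with edgeR, 395 with DESeq2, 36 at a mean of at least 500, and 0 with the chimera as block (Nphs1 adjusted p = 0.0628), without a filter, or without any 1 of the 8 libraries.

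KO donor against the mean of the other 3 groups asks what sets these libraries apart from all those without the Etv3-/- label. Cd86 rose by 1.66 (adjusted p = 0.00375), Cd80 by 2.07 (adjusted p = 0.00347), Il12b by 1.72 (adjusted p = 0.0179) and Cd274 by 1.34 (adjusted p = 0.0408), the last to 103740 ± 1356 from group means between 36261 and 55745. Aldh1a2 fell by 1.85 (adjusted p = 0.0282), and Ccl17, a chemokine that attracts regulatory and helper T cells, fell by 1.27 (adjusted p = 0.0358). Cholesterol genes had 13 falls and 0 rises among 24 (0 and 19 adjusted over the list alone; median -1.68, camera adjusted p = 1.89e-19, adjusted p = 0.0471 with an estimated correlation).

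Klhl4 and Oit1 had 0 reads in all 6 other libraries and 195 ± 154 and 132 ± 55.7 normalized counts in KO donor. Stac (1838 ± 194), Col4a2 (1602 ± 693) and Scx, a tendon transcription factor (446 ± 302), were the other leading rises. Itgb2l, Kirrel2 and Bpifb2 had 0 reads in KO donor, and Lamc2 and F9 had 1.84 and 3.68 normalized counts, all in KO donor 1. Without KO donor 1 and 2, Klhl4 stood at 304 and 86.0 and Scx at 660 and 232. In all, 508 genes differed, 271 higher and 237 lower (2458 at an unadjusted p under 0.05), and 31 of these had a group mean of 0. With edgeR the count was 397, of which 280 were higher (70.5% against 53.3%), with DESeq2 it was 1313, and without a filter 316. Most of the 508 calls were lost when any 1 library was left out, which leaves a group of 1, and all were lost without KO donor 2. Without KO donor 1 the genes still called were mostly lower in KO donor. All 508 kept their sign in these fits, but they were chosen by their p in the same libraries, so this adds no evidence.

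**Figure D2:**
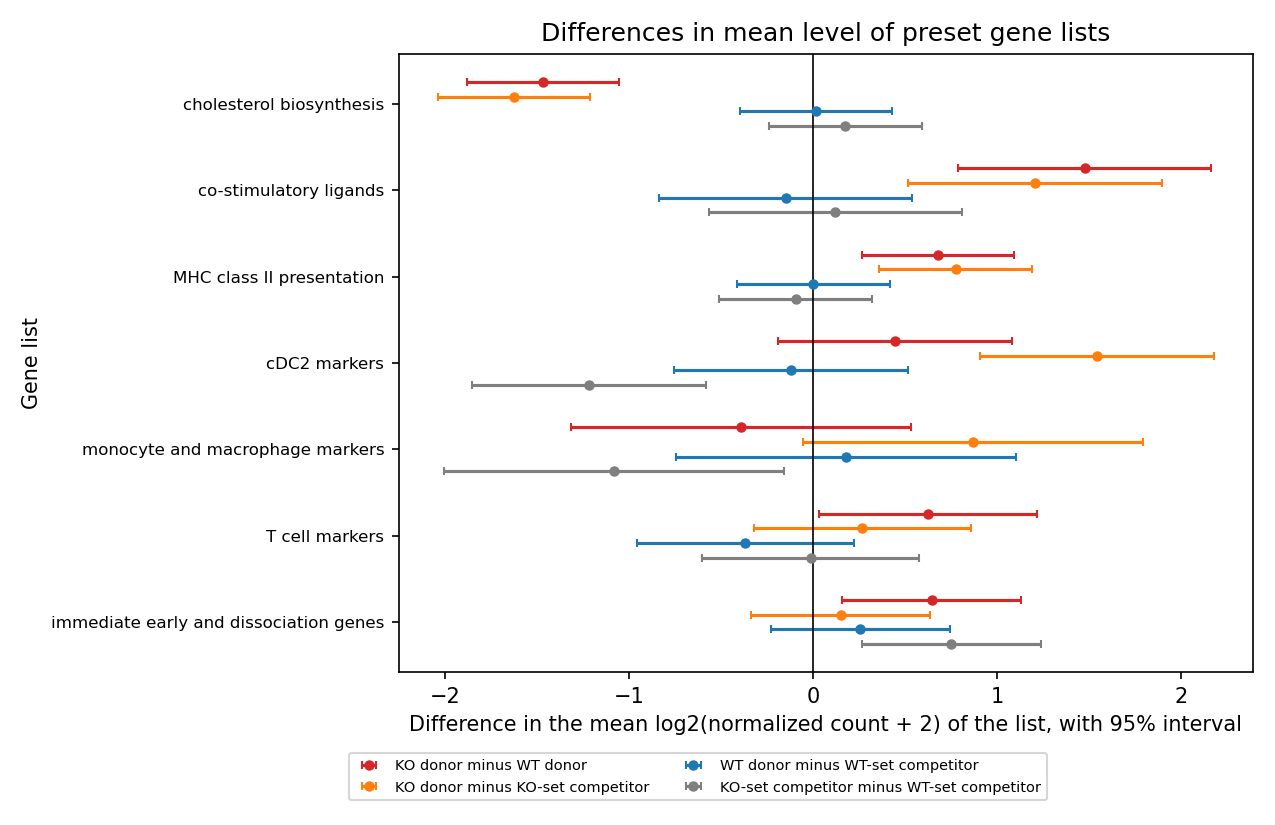
Differences in the mean log2 level of 7 gene lists (horizontal axis) for 4 comparisons between groups of 2 libraries, as points with 95% confidence intervals from limma. Cholesterol biosynthesis lies at -1.47 for KO donor against WT donor and at 0.016 for WT donor against its competitor, and immediate early genes lie at 0.75 between the 2 competitor groups.

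WT donor against WT-set competitor is the control for the CD45.2 and CD45.1 origin of the cells, with no difference in Etv3. No gene passed limma's test (0 called, 501 at an unadjusted p under 0.05, smallest adjusted p = 0.0798; 0 with edgeR and 71 with DESeq2). Cholesterol genes had a median of 0.03 (0 calls among 24, 0 adjusted over the list alone, camera adjusted p = 0.998), and their mean log2 level differed by 0.016 (95% interval -0.40 to 0.43). Closest to the threshold, without passing, were Cxcl1, a neutrophil attractant, at 80142 ± 51517 against 5255 ± 480 (log2 3.77, adjusted p = 0.0798), and Cnbd2 at 22016 ± 6328 against 4173 ± 17.9 (log2 2.37, adjusted p = 0.0798). These were the 2 genes called with a pseudocount of 8 or a mean of at least 50 or 500.

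Further genes that did not pass were Cep85 (1.62), Stk25 (1.298) and Zfp459 (at least 128-fold) on the higher side. On the lower side they were Csrp1 (-1.61, adjusted p = 0.297), Mpp7 (-2.73), Glb1l2 (at least 157-fold), Plagl1 (at least 200-fold) and Evc2 (at least 195-fold). Markers of plasmacytoid dendritic cells had a median of -1.06, and -0.51 without WT donor 2, with 0 calls among 17 (0 adjusted over the list alone; camera adjusted p = 1.59e-09, adjusted p = 0.462 with an estimated correlation). B cell markers had a median of 0.42, and 0.10 and 1.08 without WT donor 1 and 2, with 0 calls among 23 (1 and 0 adjusted over the list alone; camera adjusted p = 1.26e-05, adjusted p = 0.702 with an estimated correlation). T cell markers had a median of -0.27, and -0.61, -0.082 and -0.42 without WT-set competitor 1, WT-set competitor 2 and WT donor 2, with 0 calls among 24 (0 adjusted over the list alone; camera adjusted p = 0.000481, adjusted p = 0.702 with an estimated correlation), a call lost without WT-set competitor 2 or WT donor 1 (adjusted p up to 0.734). The B cell call was lost without WT-set competitor 1 or WT donor 1 (adjusted p up to 0.987 over all alternatives). Ribosomal protein genes had a median of -0.29 (0 calls among 83, 0 adjusted over the list alone; camera adjusted p = 1.59e-09, adjusted p = 0.797 with an estimated correlation), which became -0.70 without WT-set competitor 1 and turned to 0.094 without WT-set competitor 2. Immediate early and dissociation genes had a median of 0.25, and 0.16 and 0.41 without WT donor 1 and 2, with 0 calls among 30 (0 adjusted over the list alone; camera adjusted p = 0.00285, adjusted p = 0.702 with an estimated correlation), a call lost without WT-set competitor 1 or WT donor 1 (adjusted p up to 0.417).

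KO-set competitor against WT-set competitor compares cells without the Etv3-/- label that grew beside donor cells with and without it. No gene passed limma's test (0 called, 701 at an unadjusted p under 0.05, smallest adjusted p = 0.417; 0 with edgeR and 79 with DESeq2). Immediate early and dissociation genes had 0 calls among 30 (11 and 0 adjusted over the list alone) and a median of 0.66 (camera adjusted p = 1.97e-15, adjusted p = 0.135 with an estimated correlation). Their mean log2 level differed by 0.75 (adjusted p = 0.083). Without passing, the heat-shock genes Hspa1a (232730 ± 83566 against 41839 ± 20322) and Dnajb1 (60844 ± 13728 against 21315 ± 1950) differed by 2.52 (adjusted p = 0.515) and 1.498 (adjusted p = 0.469).

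Markers of cDC2 cells had a median of -0.91 (0 calls among 24, 0 and 4 adjusted over the list alone; camera adjusted p = 1.44e-07, adjusted p = 0.125 with an estimated correlation). Monocyte and macrophage markers had a median of -0.82 (0 calls among 27, 0 and 2 adjusted over the list alone; camera adjusted p = 5.47e-09, adjusted p = 0.191 with an estimated correlation). Markers of plasmacytoid cells had a median of -1.04, and -0.63 without KO-set competitor 1 (0 and 3 adjusted over the list alone; camera adjusted p = 3.00e-10, adjusted p = 0.135 with an estimated correlation). Those of natural killer and innate lymphoid cells had one of -0.94, and -1.99 and -0.30 without WT-set competitor 1 and 2 (0 and 3 adjusted over the list alone; camera adjusted p = 5.47e-08, adjusted p = 0.322 with an estimated correlation). B cell markers had a median of 0.59, and 0.92, 0.37 and 0.88 without WT-set competitor 2, KO-set competitor 1 and KO-set competitor 2 (4 and 0 adjusted over the list alone; camera adjusted p = 8.80e-07, adjusted p = 0.59 with an estimated correlation). Cholesterol genes had a median of 0.17 (0 calls among 24, 0 adjusted over the list alone; camera adjusted p = 0.293). Other genes that did not pass were Tcaf2 (1.82), Tnfsf15 (2.77, adjusted p = 0.918) and Zfp459 (at least 124-fold) on the higher side and, on the lower side, Cd209b, a lectin (117 ± 39.5 against 1603 ± 333, adjusted p = 0.417). With 0 reads in the KO-set competitor, and also not passed, were Il17f (at least 332-fold), Trem1 (at least 229-fold), Gzma, a granzyme (at least 1296-fold), and Fcgr1 (at least 90.5-fold). Without WT-set competitor 1 and 2 the bounds were 479 and 184 for Il17f and 2279 and 313 for Gzma, and without KO-set competitor 1 and 2 they were 173 and 74.5 for Zfp459.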

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

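The tests of handling and of donor origin for the cholesterol genes were chosen only after the result was seen. Each result here is one for which the donor effect of the KO set differed from that of the WT set in a test of the difference itself. For Nphs1, the single gene called, the difference was -7.88 on the log2 scale, from 25.03 ± 5.87 normalized counts in KO donor (n = 2) and group means of 4320 to 5858 elsewhere. For gene lists, camera at its preset correlation gave the call, and none of the lists was called with an estimated correlation, where cholesterol biosynthesis and cDC2 markers came closest (adjusted p = 0.0542 for each). The median differences of the lists were 0.93 for co-stimulatory ligands, 0.67 for inflammatory cytokines, 0.35 for interferon-stimulated genes, 0.95 for MHC class II genes and 0.50 for migration genes. They were 1.00 for cDC2 markers (1.14 with the member that had 0 reads in a group at its bound), 0.58 for Langerhans cell markers, 1.15 for plasmacytoid cell markers, 1.18 for monocyte and macrophage markers and 0.98 for natural killer and innate lymphoid markers. They were 0.61 for T cell markers, -0.82 for B cell markers, -0.58 for cell cycle genes, -1.73 for cholesterol biosynthesis, 0.43 for nuclear oxidative phosphorylation genes, -0.97 for the 4 measured sex-linked genes and 0.56 for ribosomal protein genes. For plasmacytoid markers the WT-set competitor libraries stood apart, with mean log2 levels of 11.94 and 11.47 against 10.53 to 10.96 in the other 6, and KO donor differed by -0.07 from WT donor and from its own competitor. For the cDC2, monocyte and natural killer lists the KO-set competitor libraries were the lowest of the 8. The size of the ribosomal difference depended on WT-set competitor 2, which stood apart at 13.36 against 12.56 to 13.06 in the other 7. Leaving out WT-set competitor 1 or 2 gave 0.94 or 0.19 for ribosomal genes, 0.69 or 0.28 for oxidative phosphorylation and -1.05 or -0.09 for cell cycle. Without WT-set competitor 1 the medians were 1.15 for T cell, 0.30 for Langerhans and 0.21 for interferon genes, and without WT-set competitor 2 it was 0.30 for natural killer markers. Without WT donor 1 they were 0.55 for natural killer, 0.31 for Langerhans, -0.46 for B cell, -0.10 for cell cycle and -0.64 for sex-linked genes, and without WT donor 2 they were 0.58 for plasmacytoid, -1.31 for B cell and -1.36 for cell cycle genes. Without KO-set competitor 1 they were 0.39 for cytokines, 0.36 for T cell and 0.46 for natural killer markers, and without KO-set competitor 2 it was -0.61 for sex-linked genes. Without KO donor 1 it was -0.47 for sex-linked genes, and without KO donor 2 it was 0.57 for co-stimulatory ligands. The cytokine, interferon, cell cycle, sex-linked, B cell and natural killer lists lost this call in at least 1 alternative, with adjusted p-values up to 0.189, 0.136, 0.585, 0.406, 0.2 and 0.315. Groups of 2 libraries are too small to test a single library against its group.

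Genes of cholesterol biosynthesis were lower in KO donor than in all 3 other groups, by 1.47 against WT donor in mean log2 level (-1.47, 95% interval -1.88 to -1.05). Handling or environment of the KO set is argued against, since its competitors differed from those of the WT set by 0.176 (-0.238 to 0.590), where the explanation needed -0.734 or lower. The CD45.2 origin of the cells is argued against by the WT set, in which donor and competitor differed by 0.0162 (-0.398 to 0.431) against a needed -0.814. Transcript length and GC content are argued against, since the list's median moved only from -1.48 to -1.56 when their trend was removed. The trend was weak (r squared 0.015), and the list had a median length of 3268 bases and 49.2% GC, against 3092 and 49.7% for the tested genes. Removing it could therefore move the median only a little. The corrected median lay below all 10000 random lists matched on expression (95% of them within -0.162 to 0.266). This repeats the fall of the list in the same libraries and adds no evidence. Lower cholesterol synthesis as an effect of the Etv3-/- label stays open as a hypothesis, and other routes, such as more sterol taken up by these cells, were not tested. RNA of Ldlr, the receptor for low-density lipoprotein and a member of the list, was itself lower in KO donor than in WT donor (log2 -2.28). As part of the same pattern, this value does not speak for or against uptake, which was not measured.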

How the results depend on the processing

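A filter at a mean of 500 was the only alternative chosen after the data were seen. Each library left out in turn made a group of 1, which is assumed to vary like the others, and left fewer degrees of freedom. KO donor against WT donor gave 272 genes, 121 without a filter, 0 with only the compared groups, 170 with edgeR, 1037 with DESeq2 and 0 to 45 with a library left out. KO donor against KO-set competitor gave 207, and 112, 0, 119, 876 and 0 to 16 in the same order. Against all other groups KO donor gave 508, 316 without a filter, 1313 with DESeq2 and 0 to 191 with a library left out. The difference of donor effects gave 1, 0 without a filter, 36 at a mean of 500 (22 higher, 14 lower), 395 with DESeq2 and 0 with any library left out. The 0 between WT donor and its competitor became 2 with a pseudocount of 8, 2 at a mean of 50, 2 at a mean of 500 and 71 with DESeq2, and the 0 between the competitors became 79 with DESeq2. With fewer genes or libraries in a test its threshold moves by construction, and the cause of the differences between the tools was not tested. DESeq2 gave no adjusted p for 938 to 1250 genes in the 4 comparisons with KO donor and for 0 in the other 2.

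The replicate block by chimera gave 96 genes for KO donor against its competitor and 0 for the difference of donor effects. Of the named results it ended the calls given in the report and those of Tnfrsf9, Itgax, Cxcr4, Sting1, Elk3 and the helper T cell list (adjusted p from 0.0510 to 0.0885), and it added Il1b and the B cell, erythroid and sex-linked lists, changing no other call. A block by replicate number alone gave 195, 160, 0, 1, 0 and 402 genes in the 6 comparisons.

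No named gene reversed. Leaving out 1 library reversed the camera direction of 3 lists as follows, and the cause was not tested. In medians, cell cycle ran from -0.109 (without WT donor 1) to 1.06 between WT donor and its competitor and from -1.36 to -0.0874 in the difference of donor effects, where the direction turned without WT donor 1 but the median stayed negative (-0.0965). Oxidative phosphorylation ran from -0.516 to -0.0412 in the former, negative throughout, and from -0.433 to 0.104 between the competitors. Ribosomal genes ran from -0.700 to 0.0943 and from -0.523 to 0.278, with the high end of these 4 ranges without WT-set competitor 2. Of the other outcomes for named genes, 7659 were unchanged, 242 passed newly and 1599 no longer passed, and for lists 2052, 42 and 100. Etv3 between KO donor and WT donor stayed at -0.142 to -0.083 and the number of lists called there at 10 to 17 with a library left out. The smallest library held 129334701 reads, and what fewer or more reads would change was not tested. A fold against a group with 0 reads is only a lower bound, and 24 of the 272 and 23 of the 207 calls had 0 reads in at least 1 of the 4 groups.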

Other observations

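Both tests of the immediate early genes, the comparison of T cell with B cell markers and the test of neighbouring genes were chosen only after the result was seen, and so were the genes named in this part. The genes below are some of the most abundant ones called in both comparisons of KO donor. Fgr, a Src-family kinase, stood at 58106 ± 2080 in KO donor and 8052 ± 136 in WT donor (log2 2.85, and 2.55 against the KO-set competitor), and Syk, a kinase downstream of Fc and C-type lectin receptors, at 58004 ± 3230 and 18723 ± 1435 (1.63 and 1.63). Lcp2, an adaptor, rose by 2.03 and 1.75, Themis2 by 2.35 and 2.20, and Grap by 2.25 and 1.98. Cd82, a tetraspanin, reached 241100 ± 29184 from 43747 (2.49 and 2.08), and F11r, a junction adhesion molecule, rose by 2.47 and 2.10. Clu, which encodes clusterin, fell from 201790 ± 57486 in WT donor to 17695 in KO donor (-3.53, and -2.54 against the competitor), and Rnf19a, a ubiquitin ligase, fell by 1.98 and 1.80.

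Ldlr, the receptor for low-density lipoprotein and a member of the cholesterol list, stood at 6078 ± 2374 in KO donor, 28855 ± 6649 in WT donor and 36569 ± 1956 in the KO-set competitor (-2.28 and -2.64), and Hmgcr, of the same list and the rate-limiting enzyme of cholesterol synthesis, at 11218 ± 3259 and 38917 ± 1691 in KO donor and WT donor (-1.82, and -1.64 against the competitor). Gpx1, an antioxidant enzyme (1.56 and 1.52), Capg, an actin-capping protein (1.70 and 1.54), Lgals3, which encodes galectin-3 (1.4995 and 1.81), and Cfp, which encodes the complement regulator properdin (2.64 and 2.83), rose in both. The Cfp differences were 1.98 and 2.18 without KO donor 1 and 3.30 and 3.49 without KO donor 2. All genes named so far in this part passed limma's test in both comparisons, with both KO donor libraries on the same side of each group they were compared with.

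Immediate early and dissociation genes had 2 of 30 members called between KO donor and WT donor and 0 of 30 between the competitors, while camera called the list upward in both, a call lost with an estimated correlation (adjusted p = 0.246 and 0.135). In mean log2 level the differences were 0.646 (95% interval 0.159 to 1.13, adjusted p = 0.126) and 0.752 (0.265 to 1.24, adjusted p = 0.0834), and the donor effects of the sets were not called as different (median difference -0.09, camera adjusted p = 0.774), while camera also called the list upward between WT donor and WT-set competitor (median 0.25, camera adjusted p = 0.00285, adjusted p = 0.702 with an estimated correlation). Handling or batch of the KO chimera set and an effect of the donor cells on their neighbours cannot be told apart, since both would raise the competitors of that set and the labels give no day or batch. A change inside KO donor cells alone would not raise the competitors of that set. Whether KO donor cells hold a further rise of their own was left undecided, since KO donor differed from its competitor by 0.151 (-0.337 to 0.638). Klf2 and Dnajb1, called between KO donor and WT donor, stood at 40315 ± 5076 and 60844 ± 13728 in the KO-set competitor too (n = 2).

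A chance split of these libraries is argued against for the calls that separate KO donor from the other 6, but only as far as 28 splits allow. Of the 28 splits into 2 and 6, 1, the real one, gave as many calls (639 in a fit of 2 groups). The highest other split, WT donor 1 with KO donor 2, gave 11. No stronger result than 1 of 28 was possible. Every other split leaves at least 1 KO donor library among the 6, so a true difference would also lower their counts. Passenger variants carried along with the Etv3 allele could not be settled. Within 10 Mb of Etv3 lay 2.20% of the 499 calls with a position (exact 95% interval 1.11% to 3.91%), but with 243 tested genes there the share could not pass 48.7%. Of the genes in this window 4.53% were called, against 3.14% of the other genes with a position (Fisher's exact p = 0.197). The 11 called there were Bnipl, Cd1d1, Cd1d2, Efna1, Fcrl1, Fdps, a gene of sterol synthesis, Il6ra, Lmna, Pbxip1, Plekho1 and S100a6. Of these, the neighbours Cd1d2 and Cd1d1 started at 86986551 and 86995834, and Etv3 at 87525407. Whether a linked variant changed any of them was not tested. Variants acting on genes elsewhere would not be seen. A larger share of other cell types in the KO donor sort could not be settled, since T cell markers moved above B cell markers by 0.907 with an interval of -0.375 to 2.19. This test did not cover a rise of T cells alone. Mast, basophil and eosinophil markers differed by -2.57 between KO donor and WT donor (-4.67 to -0.48, adjusted p = 0.126). Of their 13 measured members, 7 had 0 reads in a group. WT donor 1 was their highest library, at 8.14 against 4.12 to 6.75, and the highest for B cell markers (13.47). What stays open is an effect of the genotype label, passenger variants, a different mix of dendritic cell subsets or of other cell types, and any feature that only these 2 libraries share.

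Several genes called in KO donor against the other groups lay side by side on the chromosome and moved in the same direction. Among 11548 pairs of neighbouring tested genes within 50 kb, 31 had both members called in the same direction, against a mean of 5.74 (2 to 11 in 95% of draws, highest 17) when the calls were placed at random 10000 times (permutation p = 1e-04, the smallest these draws can give). Neighbouring genes may therefore change together in these libraries, a hypothesis found and tested on the same data. Examples were Aplp1, Kirrel2 and Nphs1 (-1.57, 0 reads in KO donor, and -7.52), Clu and Gulo (-3.13 and -5.58), Plgrkt, Cd274 and Pdcd1lg2 (1.10, 1.34 and 1.59), and Itgam and Itgax (2.39 and 1.79). Shared reads could add to the count for overlapping genes, of which Nphs1 with Nphs1os, Abi3 with Gngt2, Apobr with Il27 and Col4a1 with Col4a2 are examples, and this was not tested further. Random placement also treats all genes as interchangeable, although related genes such as H2-Eb1 and H2-Eb2 lie side by side. A run such as Aplp1, Kirrel2 and Nphs1 counts as more than 1 pair. The excess was therefore not shown to be particular to these libraries.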
